A study of Homo sapiens with 8 samples.

How the data were processed

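RNA-seq was carried out on 6 libraries from cells labelled HepG2, a human line derived from a liver tumour. Per the labels' protocols, cells received a non-targeting control siRNA (siNC, 3 libraries) or an siRNA against XBP1 (siXBP1, 3 libraries). By the same protocols, all were treated after 2 days with 30 nM thapsigargin for 3 hours. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER) and so sets off the unfolded protein response. Libraries were made with a strand-specific TruSeq kit, per the labels' protocols. The submitters' processing notes name STAR 2.5.2a, featureCounts 1.5.0 of the Subread package and the hg38 build. The strand setting of the counting and the gene annotation are not given in the sources used here. The 2 XBP1s ChIP-seq samples of the series, for which the notes name FastQC 0.11.9, Bowtie2 2.4.3, HOMER and deepTools 3.5.1, were not analysed here.

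The deposited table holds whole-number read counts per gene, not normalized, with 18555 NCBI Gene IDs in rows and 1 column for each library. A further short text that describes the files was not used. RefSeq names of GRCh38.p14 were found for 18526 IDs. The other 29 held 0.00349% of the counts and kept their ID as a name. Every row had at least 2 counts in total. Column names match sample titles, and no column was left without a sample. Total counts ran from 38209972 to 38890070 per library, a ratio of 1.018, so that 3 counts, taken as the floor, correspond to 0.077 to 0.079 CPM (counts scaled to the same library total). Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Among counts from 1 to 40, even values made up 75.8% to 80.5%, as when both mates of most read pairs are counted, so the number of fragments is probably below the number of counts. No pair of replicates agreed within sampling noise, and each library was used as 1 replicate. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

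Groups and replicate numbers were taken from the sample titles. Genes were kept with edgeR's filterByExpr, normalized with TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with group as the only term and 4 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts divided by the library total, given as mean ± SD over 3 libraries.

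The 29 gene lists were fixed before the data were examined, and 854 of their 893 genes have a row in the table. Lists of at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, and again with a correlation estimated from the residuals. fry was run as another set test. List p-values were adjusted over the lists. Members were counted by the calls over all genes and as adjusted over the list alone.

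The rule for named genes was also fixed before the data were examined. It takes XBP1, LEF1, HSPA5, DNAJB9, DDIT3, ERN1, ATF6, CTNNB1 and MYC whatever their values. It adds up to 8 genes per direction with the largest change among called genes with a mean of at least 5 CPM and no overlap between groups. For each list it adds the called members with the largest change, up to 4 for a list called by camera and up to 2 for another, or, with no called member, the 2 with the highest mean CPM. Because the planned test called a single gene, the same rule was applied again to the fit with the first principal component as a covariate. Genes named from that fit, and cell type genes named for their level, were therefore chosen after their values were seen.

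Principal components were computed on centred log2 CPM of 11528 genes with a mean of at least 100 counts. Alternatives fixed before the data were examined were size factors, upper-quartile factors or library size alone in place of TMM, no filter on low counts, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, an adjusted p under 0.01, and camera with an estimated correlation or fry for the lists. Chosen after seeing the data were the score on the first component as a covariate, leaving out both libraries at the ends of that component, and halving the counts.

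The procedure was tested on 3 simulated data sets of 14108 genes, in which 200 genes differed between siXBP1 and siNC and a gradient like the first component was present. Counts were drawn with the spread and gradient of the fit with the covariate. Results with the covariate are therefore a best case for data with that gradient. Without the covariate, 4.48% of genes changed by 0.5 on the log2 scale, 61.2% of those changed by 1 and 87.9% of those changed by 2 were recovered, with 0% false calls. With the covariate these shares were 66.2%, 85.1% and 94.4%, and 7.88% of calls were false. Without a gradient in the simulated data, the fit without covariate recovered 67.2%, 83.6% and 94.9%, with 3.16% false calls, and the fit with the covariate made 0 calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots. No genome sequence was used, so the base composition of genes was not measured.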

Results

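The series addresses how XBP1s, the spliced and active form of the unfolded protein response factor XBP1, acts with the Wnt pathway factor LEF1 in hepatocellular carcinoma cells. RNA-seq compared 3 siNC libraries with 3 siXBP1 libraries, all from cells labelled HepG2 and treated with thapsigargin, so the comparison concerns the loss of XBP1 under ER stress. There was no arm without thapsigargin among the RNA-seq samples. Library totals lay between 38209972 and 38890070 counts, and 16162 to 16769 genes had at least 1 count.

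XBP1 mRNA (gene ID 7494, chromosome 22, 28794560 to 28800569, GRCh38) was lower in all 3 siXBP1 libraries. The siNC libraries held 21455, 19495 and 19240 counts and the siXBP1 libraries 11158, 11587 and 10554. In CPM the means were 518 ± 29.5 and 288 ± 11.4 (SD, n = 3 each), so the siXBP1 mean was 55.7% of the siNC mean. XBP1 fell by 0.84 on the log2 scale (SE 0.08, edgeR adjusted p = 0.0331). With each library left out in turn the log2 fold change lay between -0.88 and -0.80, but the adjusted p exceeded the threshold without siNC replicate 2 (0.175), siNC replicate 3 (0.213), siXBP1 replicate 1 (0.475) or siXBP1 replicate 2 (0.284). Gene counts do not separate spliced from unspliced XBP1.

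The transcripts that characterise hepatocytes were near the detection floor in all 6 libraries. Of 47 genes for hepatocyte secreted proteins, 8 had a mean of at least 1 CPM, and the median over the list was 0.0736 CPM. The highest level in any library was 0.155 CPM for AFP (alpha-fetoprotein), 0.104 for TF (transferrin), 0.416 for SERPINA1 (alpha-1-antitrypsin) and 0.523 for HNF4A, a hepatocyte transcription factor. A2M (640 ± 22.5 CPM, SD, n = 6) and C3 (202 ± 12.9 CPM, n = 6) were the exceptions with high levels. The keratins KRT17 (3360 ± 409 CPM) and KRT7 (1470 ± 189 CPM) were abundant (n = 6 each). Both belong to the list of markers of other epithelial lines, in which 5 of 11 genes had a mean of at least 1 CPM. KRT8 (1210 ± 146 CPM), VIM (1180 ± 70.4 CPM) and CDH2 (167 ± 13.8 CPM), which are not in that list, were abundant too (n = 6 each). CDH1 and EPCAM, which epithelial cells express, reached no more than 0.624 and 0.103 CPM. Every statement below therefore concerns cells labelled HepG2.

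**Figure D1:**
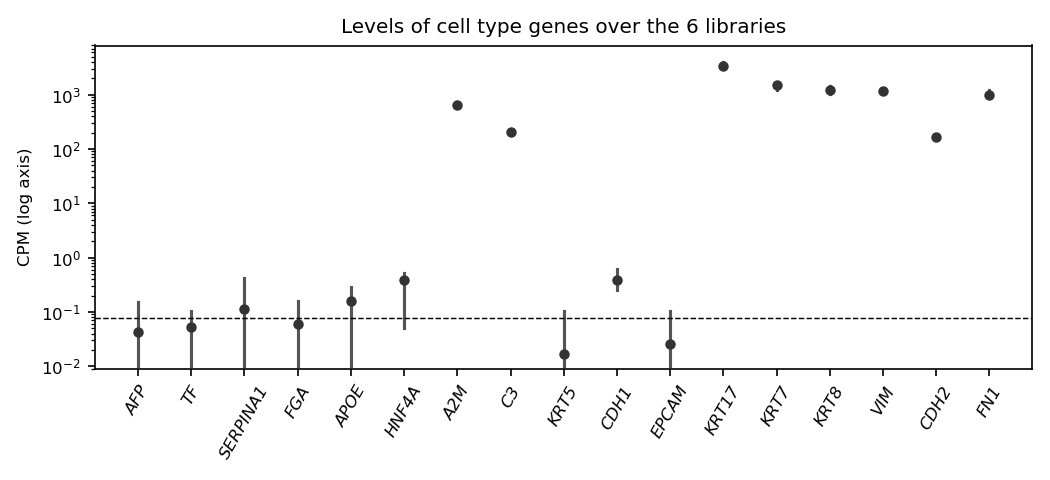
Level of cell type genes in the 6 libraries, in CPM on a log axis. Points are means over 6 libraries, lines run from the lowest to the highest library (zeros drawn at the lower end), and the dashed line is the floor of 3 counts; AFP, TF and EPCAM lie at or near the floor while KRT17 has a mean of 3360 CPM.

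Among 14337 genes tested, XBP1 alone passed the threshold, with 0 genes higher and 1 lower in siXBP1, and no gene passed with a change of at least 2-fold. At an unadjusted p under 0.05, edgeR gave 517 genes, 273 higher and 244 lower, and the next adjusted p after XBP1 was 0.474. DESeq2 called 16 genes, 7 higher and 9 lower, 1 of them at least 2-fold. The groups did not overlap for 1255 genes, or 8.75% of those tested, where chance gives 10%. The libraries differed along a first principal component that held 59.1% of the variance and correlated at -0.22 with group. It placed siNC replicate 1 (0.643) and siXBP1 replicate 3 (-0.648) at opposite ends, with the other libraries between -0.29 and 0.239. The second component, with 15.3% of the variance, kept the groups apart, with siNC libraries from -0.424 to -0.251 and siXBP1 libraries from 0.152 to 0.731.

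**Figure D2:**
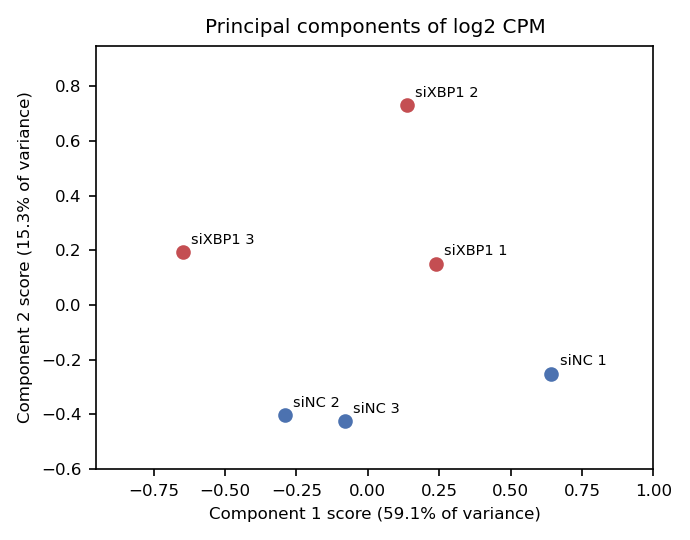
Scores of the 6 libraries on the first and second principal components of log2 CPM, without units, in blue for siNC and red for siXBP1. The first component (59.1% of the variance) runs from siXBP1 replicate 3 to siNC replicate 1, and both groups lie on both sides of 0, while the second (15.3%) has all siNC libraries below and all siXBP1 libraries above 0.

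Genes of the secretory pathway, many of them textbook targets of XBP1s, were lower in siXBP1 as groups. Of 36 ER chaperone and disulfide formation genes, 28 had lower estimates, and the list fell (median log2 fold change -0.11, camera adjusted p = 2.8e-09; adjusted p = 0.18 with an estimated correlation). Of 26 genes of ER-associated degradation, which removes misfolded proteins, 23 had lower estimates, and the list fell (median -0.08, adjusted p = 2.3e-05; adjusted p = 0.086 with an estimated correlation). The ER translocation list fell with 24 of 30 estimates lower (median -0.10, adjusted p = 2.1e-05; adjusted p = 0.088 with an estimated correlation). The vesicle transport list (COPII and COPI) fell with 41 of 52 lower (median -0.05, adjusted p = 0.0011; adjusted p = 0.28 with an estimated correlation). N-glycosylation fell with 24 of 32 lower (median -0.07, adjusted p = 0.021; adjusted p = 0.42 with an estimated correlation). The hexosamine pathway, which makes UDP-N-acetylglucosamine, fell with 7 of 10 lower (median -0.06, adjusted p = 0.033; adjusted p = 0.30 with an estimated correlation). No member of these lists passed the test over all genes. Adjusted over the list alone, 2 genes of ER-associated degradation, 2 chaperones and 1 hexosamine gene were lower, and 0 genes of the other 3 lists passed. With 1 library left out, calls ended for N-glycosylation (median -0.04 and adjusted p = 0.218 without siNC replicate 1, 0.115 without siXBP1 replicate 3), vesicle transport (0.149 without siXBP1 replicate 1) and the hexosamine pathway (0.158 without siNC replicate 2, 0.104 without siNC replicate 3, 0.322 without siXBP1 replicate 1, 0.106 without siXBP1 replicate 2). The hexosamine call also ended with limma-voom (0.052), and the N-glycosylation call with both end libraries of the first component left out (0.797). In 2 of these fits the list's median was above 0, at 0.0057 for N-glycosylation without both end libraries and 0.014 for the hexosamine pathway without siXBP1 replicate 1.

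Hypoxia targets fell as a list, with 30 of 32 estimates lower (median -0.12, camera adjusted p = 9.7e-07; adjusted p = 0.33 with an estimated correlation), and 0 members passed adjusted over the list alone. The list also followed the first component, with a median loading of 0.664 SD, against -0.238 to 0.49 in the central 95% of 10000 random lists matched on expression and gene span. The call ended without siNC replicate 1 (median -0.05, adjusted p = 0.067) and without both end libraries of that component (median -0.02, adjusted p = 0.474).

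NF-kB, interferon and immediate early transcripts were higher in siXBP1 as groups. Of 30 NF-kB and inflammatory response genes, 27 had higher estimates and the list rose (median log2 fold change 0.24, camera adjusted p = 1.3e-16; adjusted p = 0.086 with an estimated correlation). The type I interferon response list rose with 30 of 38 estimates higher (median 0.14, adjusted p = 1.9e-08; adjusted p = 0.086 with an estimated correlation). Immediate early genes, induced quickly by many stimuli, rose with 21 of 23 higher (median 0.18, from 0.10 to 0.24 with 1 library left out, adjusted p = 1.4e-08; adjusted p = 0.30 with an estimated correlation). Smaller shifts were seen for 32 targets of Wnt, beta-catenin and LEF1, a list that rose with 22 estimates higher (median 0.08, adjusted p = 0.027; adjusted p = 0.18 with an estimated correlation). The list for epithelial-mesenchymal transition rose with 31 of 48 higher (median 0.05, adjusted p = 0.035; adjusted p = 0.18 with an estimated correlation). This list holds epithelial genes, such as CDH1 and EPCAM, as well as mesenchymal ones, such as VIM and CDH2. Its rise therefore gives no direction of such a transition. The p53 target list rose with 18 of 26 higher (median 0.12, adjusted p = 0.024; adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone, 6 NF-kB genes, 3 immediate early genes and 1 Wnt target were higher, and 0 genes passed in the interferon, epithelial-mesenchymal and p53 lists. The Wnt target and p53 calls ended without siNC replicate 2 (adjusted p = 0.106 and 0.223), siNC replicate 3 (0.071 and 0.104), siXBP1 replicate 1 (0.149 for both) or siXBP1 replicate 2 (0.107 and 0.141). The epithelial-mesenchymal call ended without any of these (0.295, 0.0685, 0.149 and 0.0744) or siXBP1 replicate 3 (0.0618), with its median at 0.07, 0.07, 0.02, 0.06 and 0.0075 in these 5 fits, and without a filter on low counts it and the Wnt call ended as well (0.104 and 0.141). In all, camera called 13 of 28 lists, 6 higher and 7 lower. It called 8 without siXBP1 replicate 1 and 0 with an estimated correlation, where the smallest adjusted p was 0.086. The estimated correlation was below the preset 0.01 for ER-associated degradation (0.0021), Wnt targets (0.0016) and the epithelial-mesenchymal list (-0.0098). For these lists the correlation itself does not account for the lost call. The other called lists had higher correlations, from 0.016 for ER translocation to 0.41 for immediate early genes. How far these account for the lost calls was not tested. fry called 3 lists as higher, NF-kB (adjusted p = 0.033), interferon (adjusted p = 0.044) and markers of endothelial cells (adjusted p = 0.015). The endothelial list, with 6 genes tested, had a median log2 fold change of 0.33 and 4 estimates higher, and did not pass camera (adjusted p = 0.16). Its median level was 0.795 CPM, and its 2 most abundant members, ESAM (-0.21) and CDH5 (-0.25), had lower estimates.

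**Figure D3:**
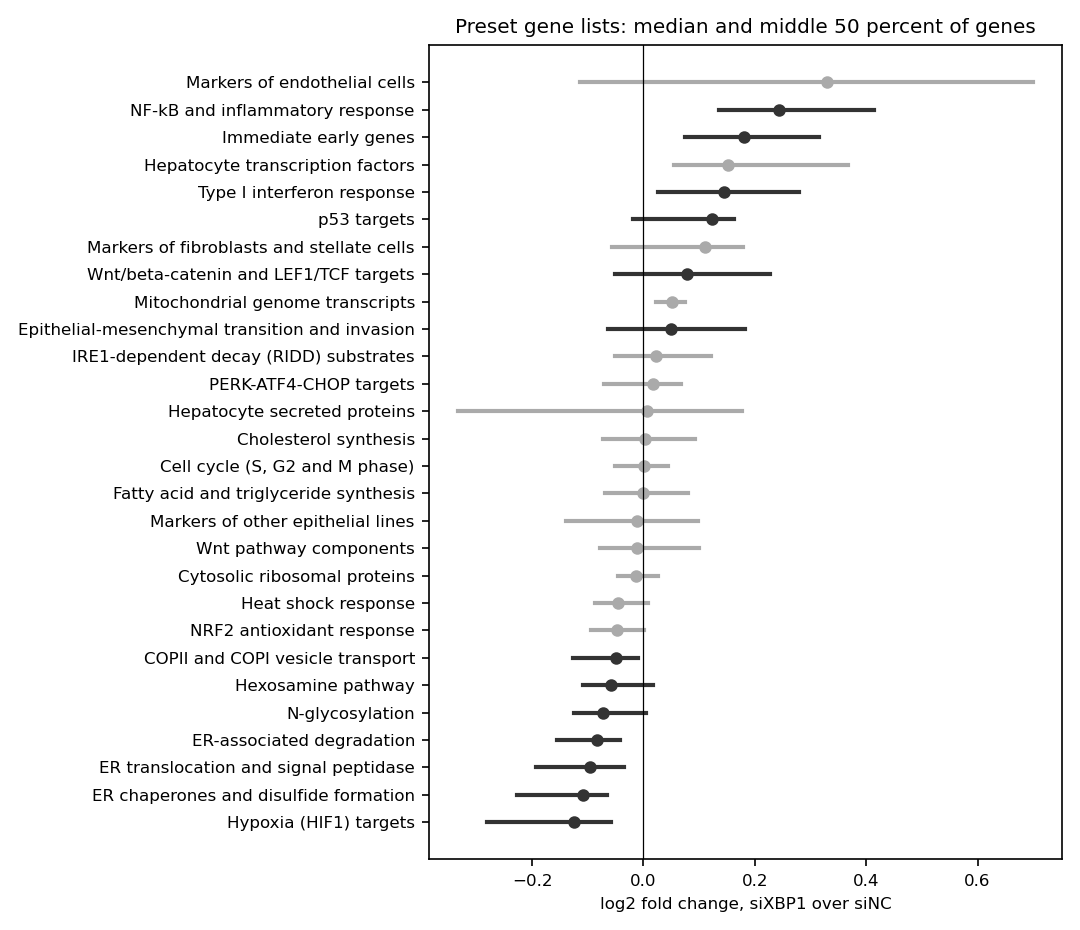
Median (point) and middle 50% (line) of the log2 fold changes, siXBP1 over siNC, of the tested genes in each preset list. Dark lists passed camera at an adjusted p under 0.05 with the preset correlation, and the NF-kB list has the highest median among these (0.24).

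Targets of the PERK arm of the unfolded protein response, substrates of IRE1-dependent decay and the genes named here showed no shift that passed the test. Of 50 targets of the PERK, ATF4 and CHOP arm, 27 had higher and 23 lower estimates, with a positive median (0.02) and mean (0.01) although camera's direction was down (adjusted p = 0.87). Of 14 substrates of IRE1-dependent decay, 7 were higher and 7 lower (adjusted p = 0.51). HSPA5, the abundant ER chaperone BiP, had 6885 ± 314 CPM in siNC and 6561 ± 356 in siXBP1 (n = 3 each), a log2 fold change of -0.07 (SE 0.07). The log2 fold changes of DDIT3 (-0.07, SE 0.11), which encodes CHOP, of ERN1 (0.30, SE 0.24), which encodes IRE1, and of ATF6 (0.06, SE 0.10) did not pass either (adjusted p = 1 each).

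LEF1 had 3, 2 and 4 counts in the siNC libraries and 1, 0 and 0 in the siXBP1 libraries, too few for a test or a fold change. CTNNB1, which encodes beta-catenin, had a log2 fold change of 0.00 (SE 0.08), and MYC one of 0.04 (SE 0.09; adjusted p = 1 for both). Wnt pathway components had 16 estimates higher and 18 lower (camera adjusted p = 0.72). Cell cycle genes had 29 higher and 29 lower (adjusted p = 0.81), fatty acid synthesis 14 and 14 (0.81), and cholesterol synthesis 12 and 12 (0.87). Heat shock genes had 7 higher and 13 lower (adjusted p = 0.15; with the first component as a covariate lower at 0.024, but 0.44 with an estimated correlation), NRF2 targets 8 and 21 (0.16), mitochondrial transcripts 11 and 2 (0.28), and ribosomal proteins 33 and 44 (0.40). The ribosomal list passed as lower without siNC replicate 2 (adjusted p = 0.00403), siNC replicate 3 (0.00701) or siXBP1 replicate 2 (2.72e-08) and as higher without siNC replicate 1 (0.000245) or siXBP1 replicate 3 (0.000902). Its genes had an estimated correlation of 0.91, far above the preset 0.01, and with it the adjusted p over all libraries was 0.93. The adjusted p was 0.81 for 14 hepatocyte secreted proteins and 0.58 for 16 hepatocyte transcription factors, XBP1 itself among the latter. Among markers of other cell types, camera gave adjusted p = 0.42 for fibroblasts and 0.45 for other epithelial lines, and 4 leukocyte genes were too few for a test.

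With the score on the first component as a covariate, an alternative chosen after seeing the data, 172 genes passed, 102 higher and 70 lower in siXBP1, 7 of them at least 2-fold. The biological coefficient of variation was 8.04% in that fit and 15.3% without the covariate. A fall was bound to follow, because the component was computed from these same 6 libraries, so it is no sign of a better fit. The fit with the covariate also takes the score as known, so its SEs and adjusted p-values may be too small. Unless another fit is named, values in this paragraph and the next are from that fit, and of the genes named only XBP1 passed edgeR's test without it. DESeq2, run without the covariate, also called DNAJB9, DERL3, UAP1, FSCN1, ETV3 and MSTO2P as lower and IL6, CXCL8, TNFAIP3, KLF6, CLDN1 and EDN1 as higher, with adjusted p from 1.99e-05 (MSTO2P) to 0.049 (ETV3 and CLDN1). In CPM, without the covariate, siNC and siXBP1 libraries overlapped for ERO1B, DNAJC3, SSR1, MAGT1, SEC23A and ASPM below. They also overlapped for OASL, DUSP5, FOSL1, JUN and PLAUR in the next paragraph. DNAJB9, an ER co-chaperone, fell from 78.3 ± 11.1 to 47.9 ± 7.55 CPM (n = 3 each; log2 fold change -0.79, SE 0.07, adjusted p = 1.85e-07). Of the chaperone list, 9 genes fell, among them ERO1B (-0.52, SE 0.10), DNAJC3 (-0.41, SE 0.06) and CRELD2 (-0.35, SE 0.07). Of ER-associated degradation, 4 fell, among them DERL3 (-0.65, SE 0.11), SYVN1 (-0.40, SE 0.06) and EDEM1 (-0.36, SE 0.06). SSR1 (-0.36, SE 0.05), SSR3 (-0.35, SE 0.06) and SEC61A1 (-0.28, SE 0.05), which serve protein entry into the ER, fell as well. ALG2 (-0.30), MAGT1 (-0.29) and SEC23A (-0.34) fell, as did UAP1 of the hexosamine pathway (-0.54, SE 0.06). FICD, which modifies BiP (-0.63, SE 0.11), the actin-bundling gene FSCN1 (-0.72, SE 0.06; 407 ± 43.3 to 235 ± 45.5 CPM) and ETV3 (-0.67, SE 0.10) fell too. MSTO2P (-0.99) and LINC00896 (-0.57) also fell, but MSTO2P is a pseudogene of MSTO1 and may share its reads. CA9 (-0.37) and SLC2A3 (-0.30) fell among hypoxia targets, and CDC6 (-0.25) and ASPM (-0.26) among cell cycle genes. CA9 had -0.49 without the covariate and -0.19 without both end libraries, and ASPM had -0.08 without the covariate (129 ± 40 and 123 ± 45.5 CPM, overlapping) and above 0 in 4 of the 6 fits with 1 library left out and no covariate.

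IL6 rose from 72.5 ± 10.2 to 127 ± 14.6 CPM (n = 3 each; log2 fold change 0.87, SE 0.07, adjusted p = 6.9e-08), and the chemokine gene CXCL8 rose from 32.7 ± 5.64 to 56.9 ± 4.96 CPM (0.83, SE 0.10). They are among 8 NF-kB genes that rose, with TNFAIP3 (0.50, SE 0.06), an inhibitor of NF-kB signalling, and NFKBIZ (0.48, SE 0.10). Of the interferon list 7 rose, among them RSAD2 (0.40), IFIT2 (0.34), IFIT3 (0.31) and OASL (0.30), and IFNL1, an interferon gene, rose by 0.74 (SE 0.16). Of the immediate early genes 8 rose, among them DUSP5 (0.60), BTG2 (0.57), ATF3 (0.47) and KLF6 (0.42). Of the Wnt target list 4 rose, CLDN1 (0.48), FOSL1 (0.38), JUN (0.34) and PLAUR (0.28). FOSL1 and JUN also belong to the immediate early list, and CLDN1 and PLAUR to the epithelial-mesenchymal list. In the latter TIMP3 (0.31) and THBS1 (0.26) rose too, as did ATF3 and TXNIP (0.24) in the PERK list. EDN1 (0.63), FGFBP1 (0.65), SALL4 (0.65) and GBP5 (0.63) were among the largest rises outside these lists, with the pseudogene GTF2IP1 (0.61). In that fit camera called 15 lists, the 13 above with heat shock genes as lower (adjusted p = 0.024) and ribosomal proteins as higher (0.007). With an estimated correlation these 2 had adjusted p = 0.44 and 0.86, and the NF-kB list alone passed (0.048). Called members exceeded the share among all genes tested for chaperones (Fisher's exact test, adjusted p = 4.2e-09), immediate early genes (4.2e-09), NF-kB (1.6e-08), interferon (2e-06), ER-associated degradation (0.0014), Wnt targets (0.0026), epithelial-mesenchymal transition (0.01) and ER translocation (0.019). Fisher's test takes genes as independent, which genes measured in the same 6 libraries are not, so these values overstate the evidence. Some lists also share called genes, such as CLDN1 and PLAUR, so their results are not separate. The count of 172 depended on single libraries, with 76 genes without siNC replicate 1, 30 without siNC replicate 2, 48 without siNC replicate 3, 349 without siXBP1 replicate 1 and 80 without siXBP1 replicate 3. Leaving out both libraries at the ends of the component, in a fit without the covariate, gave 702 genes, 124 of them among the 172 and all 124 in the same direction. Both fits share the remaining libraries, so the shared direction is no independent support. Of the 702, 209 were higher and 493 lower, so the balance of the 172 did not hold. Over all settings run, 12 of the genes named had estimates that differed by over 1.5 times from the value given. Besides CA9 (-0.64 to -0.19) and ASPM (-0.65 to 0.10), these were ERO1B (-0.81 to -0.22), MAGT1 (-0.45 to -0.10), SEC23A (-0.52 to -0.16), SSR1 (-0.53 to -0.20), DUSP5 (0.26 to 0.79), FOSL1 (0.16 to 0.52), JUN (0.10 to 0.51), PLAUR (0.15 to 0.41), IFNL1 (0.44 to 0.93) and GTF2IP1 (0.28 to 0.73).

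**Figure D4:**
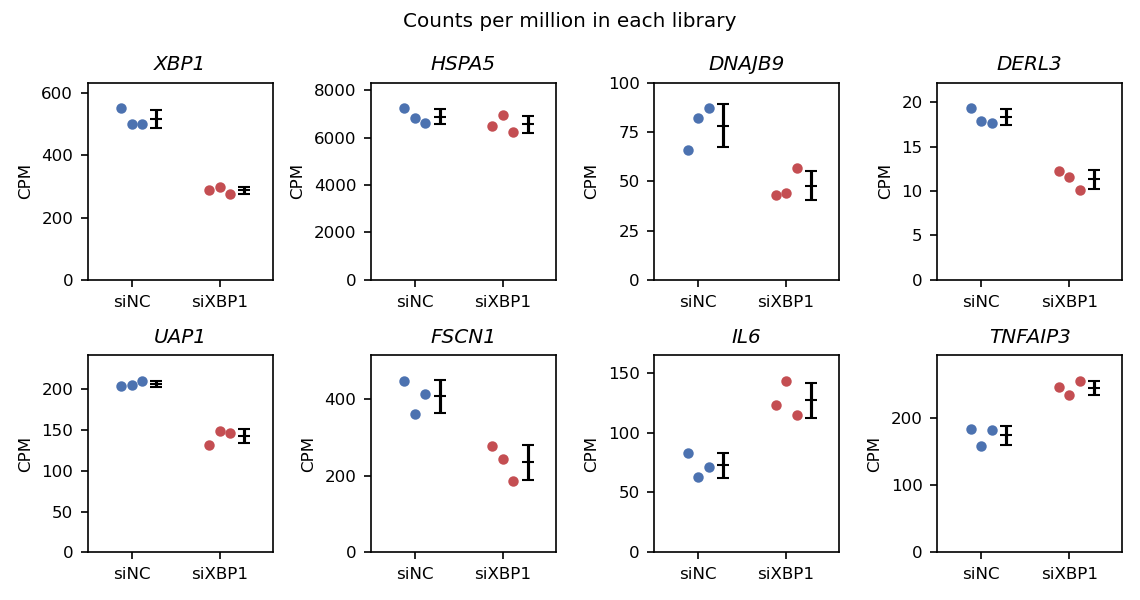
CPM of 8 genes in each of the 3 siNC (blue) and 3 siXBP1 (red) libraries, with the mean and SD beside the points and axes that start at 0. XBP1, DNAJB9, DERL3, UAP1 and FSCN1 are lower in all siXBP1 libraries, IL6 and TNFAIP3 are higher in all, and the HSPA5 groups overlap.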

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

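The first component as a covariate, the fit without both libraries at its ends and halved counts were chosen after seeing the data; the other settings were planned. XBP1 was lower under all settings run, with log2 fold changes from -0.88 to -0.76, and missed the threshold with upper-quartile factors (-0.85, adjusted p = 0.0546) and in 4 of the 6 fits with 1 library left out (range -0.88 to -0.80), which have fewer samples. The count of 1 gene became 0 with upper-quartile factors, 0 at an adjusted p under 0.01, 16 with DESeq2, 172 with the covariate, 702 without both end libraries, and 0 to 1 with 1 library left out. The count at least 2-fold, 0 as reported, was 1 with DESeq2, 7 with the covariate and 23 without both end libraries. The count of 172 ranged from 30 to 349 with 1 library left out, and was 179 with size factors and 177 with library size alone. The 13 lists became 8 at an adjusted p under 0.01, 0 with an estimated correlation, 3 with fry, which tests another hypothesis, and 8 to 12 with 1 library left out, while the covariate gave 15, heat shock genes (adjusted p = 0.0244) and ribosomal proteins added. Apart from these settings the cause was not tested. Whether the replicate numbers pair the libraries could not be told. The deviations of same-numbered libraries correlated at 0.6, -0.36 and 0.43. For siNC replicates 1 and 3 this was the best match, but siNC replicate 2 correlated best with siXBP1 replicate 3 (0.65). The deviations also hold the first component, so these correlations cannot settle the pairing. With the replicate number as a block 1 gene and 13 lists were called, and no call changed.

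The direction of the test turned in no setting run for a gene or list that had passed it, but list medians turned for N-glycosylation (0.0057 without both end libraries) and the hexosamine pathway (0.014 without siXBP1 replicate 1). With 1 library left out, medians of called lists ranged from -0.19 to -0.049 (hypoxia), -0.098 to -0.039 (N-glycosylation), 0.0075 to 0.074 (epithelial-mesenchymal), -0.11 to -0.021 (vesicle transport), -0.14 to -0.064 (ER-associated degradation), 0.046 to 0.10 (Wnt targets), 0.067 to 0.10 (p53 targets, 0.12 as reported) and 0.098 to 0.24 (immediate early genes). Directions turned for genes and lists that had not passed. Without both end libraries, log2 fold changes were 0.0071 for HSPA5, 0.073 for DDIT3, -0.079 for ERN1 and -0.041 for ATF6. For CTNNB1 they were -0.0070 with upper-quartile factors, -0.00065 with library size alone, -0.00067 without a filter and -0.0041 with halved counts. With 1 library left out they ranged from -0.044 to 0.013 for CTNNB1, -0.0013 to 0.12 for ATF6, -0.022 to 0.080 for MYC and -0.43 to 0.10 for ASPM. Where camera's direction turned, list medians without both end libraries were 0.050 (PERK targets), -0.031 (fatty acid synthesis), 0.012 (NRF2), 0.033 (mitochondrial transcripts), 0.183 (ribosomal proteins, which then passed, adjusted p = 1.15e-16, over a range of 1.15e-16 to 0.983) and 0.189 (other epithelial lines). With the covariate they were -0.0034 (PERK targets), 0.138 (hepatocyte transcription factors), 0.041 (ribosomal proteins, adjusted p = 0.00705) and 0.034 (other epithelial lines). The hepatocyte secreted list had 0.0021 with DESeq2 and 0.00049 with halved counts. The hepatocyte transcription factor list had 0.0967 with the stricter filter and 0.134 with halved counts, and PERK targets had 0.0175 with fry. With 1 library left out, medians ranged from -0.033 to -0.0017 (PERK targets), -0.041 to 0.032 (Wnt components), -0.020 to 0.024 (cell cycle), -0.019 to 0.0405 (fatty acid synthesis), -0.041 to 0.0056 (cholesterol synthesis), -0.016 to 0.093 (mitochondrial transcripts), -0.12 to 0.067 (ribosomal proteins) and -0.14 to 0.072 (other epithelial lines). The common coefficient of variation of these data was 15.3% without the covariate. Simulations with a gradient like the first component recovered 4.48% of changes of 0.5 on the log2 scale without the covariate. Smaller changes were therefore mostly out of reach.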

Other observations

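Apart from the test of neighbouring genes, the tests in this part were chosen after the results were seen. In the major histocompatibility complex region of chromosome 6, 53 protein-coding genes were measured, with a median of 0.285 CPM against 18.4 CPM for all protein-coding genes in the table, and 28.3% of them reached 1 CPM. Values of genes in this region, VARS1 among the 172 genes included, are uncertain. LUM (136 ± 13.7 CPM, SD, n = 6) and COL3A1 (129 ± 12.1 CPM), which fibroblasts express, and CD68 (41 ± 2.41 CPM), a gene of macrophages, were measured in all libraries, whose labels name a single line. The leukocyte list that holds CD68 had a median of 0.263 CPM, and 2 of its 7 genes had a mean of at least 1 CPM.

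The hepatocyte transcripts near the floor were set against technical explanations. Of the 61 nearest protein-coding neighbours of the low genes that have a row in the table, 70.5% had at least 1 CPM, against 73.9% of all protein-coding genes in the table. Neighbours without a row were passed over, and a locus with lost reads would leave such neighbours. The test therefore cannot decide whether reads were lost at these loci. Secreted proteins outside the hepatocyte list, also made at the ER, had a median of 310 CPM over 12 genes, from 0.734 (PLAU) to 995 (FN1). Such levels argue against a decay of all ER-targeted mRNA under thapsigargin. The 12 genes were picked from the epithelial-mesenchymal list after values had been seen, and they do not bear on a decay of the hepatocyte mRNAs alone. A candidate explanation is that the cells were of another line than labelled, since the hepatocyte list had a median of 0.0736 CPM while KRT17 and KRT7 were abundant in every library. The design gives no group for this, no biological explanation other than that decay was tested, and the line itself was not identified.

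Library totals differed by a ratio of 1.018, which argues against depth as the cause of the first principal component, although its end libraries, siNC replicate 1 and siXBP1 replicate 3, had the highest and the lowest total. Across protein-coding genes, which are not independent replicates, its loading had a Spearman's rho of -0.54 with genomic span. Within each of 5 span classes, loadings were higher on GC-rich than on GC-poor chromosomes, by at least 0.474 SD, so base composition and gene length may both contribute. The hypoxia list had a median loading of 0.664 SD, outside its matched random lists, so a difference in oxygen supply between cultures may contribute as well. The base composition of single genes was not matched in that test, and other lists, such as NRF2 targets (0.62 SD), also lay outside their random lists.

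For the higher NF-kB, interferon and immediate early transcripts, the list medians of log2 fold change with that component as a covariate were 0.259, 0.168 and 0.224, against 0.244, 0.144 and 0.181 without, which argues against the component as their whole cause. The interferon list nevertheless followed the component, with a median loading of -0.437 SD against -0.0466 to 0.601 in its matched random lists. A response to the siRNA molecule itself cannot be told apart from the loss of XBP1, because every siXBP1 library received the XBP1 reagent and no siNC library did. The interferon list's median of 0.144 would follow from either. An effect of XBP1 loss on these genes therefore stays open as a hypothesis.

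The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For genes called, the real split gave 1 and the highest other split 1500, so 2 splits, the real one included, gave at least 1. That other split, siNC replicate 1 with siXBP1 replicates 1 and 2 against the rest, follows the first component and so points to a structure of the samples. With the component as a covariate the real split gave 172 genes and the highest other 151, from that split again, so the real split alone reached 172. For lists called by camera the real split gave 13 and the highest other 7.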
